A study of Mus musculus with 16 samples.

How the data were processed

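The libraries are KIN-CLIP libraries, an iCLIP method in which a pulsed ultraviolet laser crosslinks an RNA-binding protein to RNA for a set time. Per the labels, they come from a monoclonal line of mouse GC-1 spg cells, a line derived from spermatogonia, that expresses the germ cell RNA-binding protein Dazl under doxycycline. RNA linked to Dazl was isolated from a gel, reverse transcribed, circularized and amplified. The series has 16 samples from 2 laser powers, 2 Dazl levels and 4 crosslinking times. The 4 samples of 0 s had no processed file here and were not analysed here, so no value has an uncrosslinked background. The other 12 libraries are 1 library per condition, with no replicates.

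Each file lists intervals of a chromosome with 1 value per interval, and has no header and no strand. The deposited values are a score, which the authors call normalized coverage. They are whole numbers from 1 to 24 per position. Per the submitters' processing notes, FastQC and Bowtie2 were used with the mm10 build, with no versions. The counting of reads, the normalization and the selection of sites are not given in the sources used here. The depth in reads is therefore unknown, no counting interval is given, and a comparison of totals rests on the authors' normalization making the libraries comparable. Coverage of 0 is not listed, and the lowest listed total of a region is 1 in 9 libraries and 2 or 3 in the others.

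Listed intervals at most 10 nt apart in any library were joined into 8338 regions. Of these, 6798 (81.5%) were exactly 17 nt long, and the rest were 10 to 150 nt long. A value summed over a region is called its coverage below. Every region had a value in all 12 libraries, so the planned filter of at least 6 libraries, and the filters set against it, removed no gene. Within the 17-nt regions the variance over positions divided by the mean lay between 0.988 and 1.008, and was inside the range of 20 simulated even layouts in 11 of the 12 libraries. Deviations of single positions from their region's mean had a mean correlation of -0.0007 over 66 pairs of libraries. Positions inside a region were therefore not interpreted, and totals of regions and genes were used.

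Region values of the libraries of 1 series were ordered more regularly than separate counts would be, and in the 2.6 mW, 4.2x series also tied, which was seen only after the tests had been run. At 2.6 mW and 4.2x Dazl, 0 of 8338 regions had a lower value at 680 s than at 30 s, where independent Poisson draws around the same values gave 1989. In the same series 3318 of the 7303 regions with at least 10 at 680 s (45.4%) had exactly the same whole value at 30 s, against 5.2% for draws around 1 mean. In the other 3 series ties were fewer than in such draws, between 0.0% and 2.5% against 5.7% to 7.6%, where the draws leave out the change with time. At 1 mW, 0 regions at either Dazl level were lower at 680 s than at 180 s, where draws gave 432 and 374. The draws take the values as counts, which they may not be, and add spread to values that already hold some. The deposited values therefore do not behave as separate measurements of each library, and a step that links libraries before deposit, such as a cap or a fitted curve, is not given in the sources used here. Every p-value below takes the libraries as independent, and may be too small or too large for that reason.

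Regions were placed in genes of the RefSeq table of GRCm38.p6, the assembly called mm10, by the span from gene start to gene end. A region counted for a gene if it lay in 1 gene only (7593 regions, 91.1%) or in 1 protein-coding gene among several (245 regions). Without strand, a region in overlapping or antisense genes cannot be given to one of them, and 314 regions in several genes and 186 in none were left out of gene totals. This gave 3203 genes, of which 3166 are protein-coding. The table holds no exons and no genome sequence was used here, so introns, untranslated regions and sequence motifs were not annotated. The intended comparisons of coverage in 3 prime untranslated regions and of GTT content were not run for that reason.

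Library totals were compared on the log2 scale with exact two-sided permutation tests. For Dazl level and laser power these exact tests flip the signs of 6 ratios of matched libraries (64 flips, smallest possible p = 0.0312). For time they permute the 3 times within the 4 combinations of laser power and Dazl level (1296 permutations). Genes were tested with limma (version 3.58.1, R 4.3.3) on log2(value + 3), where 3 is the highest over libraries of the lowest gene value. The model was additive in time, laser power and Dazl level, with eBayes trend and robust settings, and had 7 residual degrees of freedom. To these eBayes added a median of 107.09 prior degrees of freedom on values as deposited and 11.46 on the scaled values described below. Gene p-values on values as deposited thus rest mostly on spread pooled over genes of the same libraries, and may be too small. Adjusted p-values are Benjamini-Hochberg and the threshold was 0.05. Fold changes are on the log2(value + pseudocount) scale and understate the change of low genes. The residual of this model holds the interactions of the conditions, since no condition has a second library. Nothing in the labels says that libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Residuals shared by all genes of a library are not removed by testing many genes.

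The same model was run on values as deposited and after scaling by the median of ratios, which removes a change common to most genes. On the scaled values a fold change is a departure from the median gene. Interactions added a product term to the model. Gene lists were tested with camera (preset correlation 0.01) and again with an estimated correlation, for lists with at least 5 measured members. They were also tested with fry, which asks whether the members of a list change, without comparing them with other genes. Fry p-values are given unadjusted. Of 16 lists fixed beforehand, 9 were tested. On simulated values for 3203 genes, with a residual spread of 0.35 on the log2 scale, the fit on scaled values recovered 86% of genes changed 2-fold with Dazl level, 94% with laser power and 81% with time. It recovered 100%, 99% and 100% of those changed 4-fold, and called 16, 33 and 9 unchanged genes. The simulated residuals were independent, had the same spread in every gene and held no order or ties between libraries. Recovery in the real values may therefore be lower.

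Not every choice above was fixed beforehand. The size of the pseudocount and the region length used to check positions came from the data. Some tests, such as that of the laser effect against time, were chosen after results were seen. The joining of intervals and the handling of regions in several genes are not counted as fixed beforehand. The additive model, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, for each effect on scaled values, the 8 genes with the largest change in each direction among those past the threshold, with the same direction in every pair or block and a mean above the median gene. It adds the 10 genes with the highest mean coverage, the 3 highest members of each list, and Dazl itself. Alternatives were other pseudocounts and scalings, regions or the highest region in place of gene sums, plain eBayes, matched pairs as a block, a slope on log2 time, and leaving out libraries or times. Tests for whole-read counts were not run, because no read counts could be recovered from the values. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.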

Results

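KIN-CLIP coverage of Dazl on RNA was measured in GC-1 spg cells after 30, 180 and 680 s of laser crosslinking, at 1 and 2.6 mW, and at 1x and 4.2x Dazl. Each of the 12 conditions had 1 library. The series is about the kinetics of an RNA-binding protein in cells, and its design asks how coverage grows with time, with light and with protein. Total coverage ran from 11271 in the 180 s, 1 mW, 1x library to 252932 in the 680 s, 2.6 mW, 4.2x library. All 8338 regions were listed in each library, and between 94.0% and 94.4% of the coverage in 11 libraries, and 93.9% in the other, lay in the 3203 genes. Many regions stood at a coverage of 1 in the weakest libraries. Their share was 74.0% at 30 s and 80.5% at 180 s with 1 mW and 1x Dazl, 8.0% at 680 s in the same series, and 0 in the 3 other libraries of 680 s. In those 3 the lowest value was 2 (1 mW, 4.2x), 2 (2.6 mW, 1x) and 3 (2.6 mW, 4.2x), with 10.0%, 9.9% and 9.9% of regions at it, and 819 regions were at it in all 3. The 412 genes with only such regions made up 265, 319 and 194 of the genes called below, on values as deposited, for Dazl level, laser power and time, where their change is that of the lowest value.

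**Figure D1:**
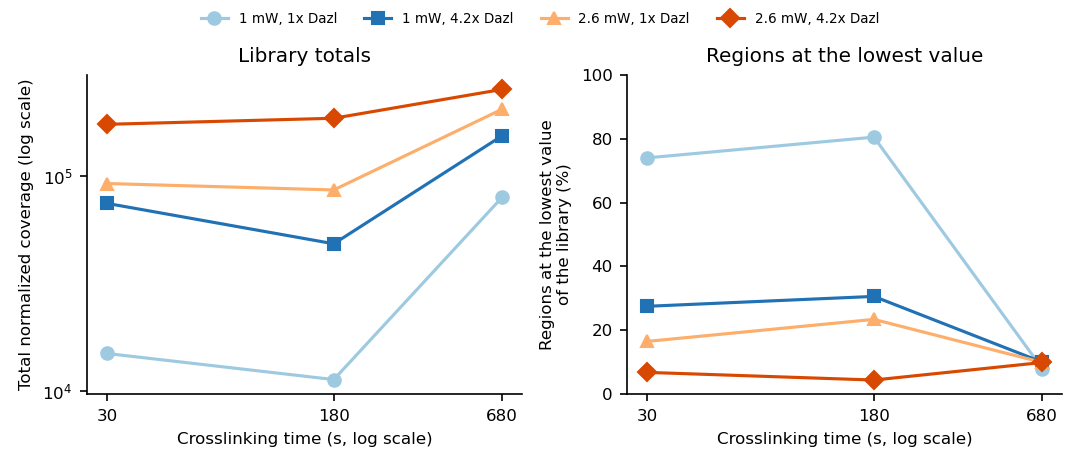
Left, total normalized coverage of each library against crosslinking time, both on log scales; right, the percent of regions at the lowest value of the library, which is 1 in 9 libraries and 2 or 3 in the others. Each point is 1 library and lines join libraries of equal laser power and Dazl level. The 680 s library is the highest of its series in each case, from 79527 to 252932.

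The RNAs with the highest mean coverage over the 12 libraries were the nuclear noncoding RNAs Neat1, which builds paraspeckles, with 891 in 62 regions, and Malat1, a nuclear speckle RNA, with 821 in 38 regions. This mean weighs most on the libraries with the largest totals. Malat1 was above Neat1 in 3 of the 4 libraries of 680 s, and Thbs1 was above Malat1 in 6 of the 12 libraries. Thbs1, an adhesive matrix glycoprotein, had 756, and Col1a1, a chain of type I collagen, had 715. Scd2, a fatty acid desaturase, had 682 with 1 of its 27 regions also in another gene, and Timp2, an inhibitor of matrix metalloproteinases, had 642. The endoplasmic reticulum chaperone Canx had 598, the disulfide isomerase Pdia3 had 523, the heparan sulfate proteoglycan Sdc4 had 474 and the membrane protein Tm9sf3 had 416. The 10 highest genes of each library held between 4.5% and 5.8% of its coverage. Neat1 and Malat1 are neighbours on chromosome 19, at 5824708 to 5845480 and 5795690 to 5802672 in mm10.

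The lists of gene groups were represented unequally. Of 52 cytoskeleton and extracellular matrix genes 33 had a region, of 53 RNA-binding protein genes 29, of 81 ribosomal protein genes 20, of 41 translation factors 16 and of 46 cell cycle genes 12. Stress and immediate early genes had 10 of 42, mRNA decay and poly(A) factors 9 of 33, nuclear and small noncoding RNAs 8 of 182, proteasome genes 6 of 31 and replication-dependent histone genes 4 of 63. Of 32 germ cell genes only Mov10l1, Rhox13 and Sall4 had a region, with mean coverages of 2.42, 1.92 and 1.67. The Rhox13 region also lies in another gene. No region was assigned to Dazl itself, so the induced gene gives no check of the Dazl levels here. Of markers of other testis cells, the Sertoli cell genes Wt1 and Dhh had 12.8 and 12.3 in 1 region each and the endothelial receptor Kdr had 4.33. No Leydig cell marker, no macrophage marker and neither of the 2 mitochondrially encoded genes of the table had a region. Whether a gene is listed rests on the authors' selection of sites, so an unlisted gene is not shown to be unbound.

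Regions lay close to gene ends. The median distance to the nearer end of the gene span was 1334.5 nt, and 42.6% of regions lay within 1000 nt of an end and 70.8% within 3000 nt. Placing regions evenly over the same gene spans would give 12.8% and 31.1%. These spans include introns, which were not annotated, so the comparison does not show a preference for the ends within spliced RNA. The ends are not told apart as 5 prime or 3 prime without strand.

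The comparison of 4.2x with 1x Dazl asks how coverage responds to the amount of protein. Coverage was higher at 4.2x on most genes. At 30 s and 1 mW, Thbs1 went from 119 to 515, Neat1 from 121 to 584, Malat1 from 53 to 440 and Col1a1 from 77 to 488. At 680 s and 2.6 mW the same genes differed less, with 1280 and 1593 for Thbs1, 1615 and 1996 for Neat1, 1639 and 1999 for Malat1, and 1269 and 1560 for Col1a1. Over all pairs Malat1 rose by 1.46 ± 0.43 (SE, log2; limma adjusted p = 0.00251) and Sdc4 by 1.61 ± 0.42 (adjusted p = 0.000808), each higher in 6 of 6 pairs. Of 3203 genes, 2640 (82.4%) were higher at 4.2x and 0 were lower, with a median change of 0.88 (1.84-fold).

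Every tested list moved up with the whole library. Of the RNA-binding protein genes 26 of 29 rose, among them the splicing factors Srsf1 (1.48 ± 0.40) and Srsf6 (1.35 ± 0.39) and the poly(C)-binding protein Hnrnpk (1.26 ± 0.40). Of the cytoskeleton and matrix genes 29 of 33 rose, of the ribosomal protein genes 18 of 20 with Rplp0 at 1.34 ± 0.38, and of the translation factors 14 of 16 with the helicase Eif4a1 at 1.40 ± 0.33, although 2 of its 5 regions also lie in another gene. Of the mRNA decay and poly(A) factors 8 of 9 rose. The deadenylase subunit Pan3 changed by 1.61 ± 0.33, the Ccr4-Not nuclease Cnot6 by 1.31 ± 0.36 and the Ccr4-Not adaptor Tob1 by 1.03 ± 0.32. Of the cell cycle genes 11 of 12 rose, including the cyclins Ccnd2 (1.28 ± 0.33) and Ccnd1 (1.14 ± 0.31) and the kinase inhibitor Cdkn1b (0.98 ± 0.33). All 8 nuclear and small noncoding RNAs, 8 of 10 stress genes and 4 of 6 proteasome genes rose. The counts were the same when adjusted over the list alone. The marker genes Wt1 (0.85 ± 0.27), Dhh (1.22 ± 0.27) and Kdr (0.65 ± 0.15) rose too. Of the germ cell genes Mov10l1 rose by 0.30 ± 0.10, while Rhox13 (0.13 ± 0.08, adjusted p = 0.131) and Sall4 (0.10 ± 0.08, adjusted p = 0.215) did not pass. No list stood apart from the other genes in the camera test, where the lowest adjusted p was 0.233 (0.799 with an estimated correlation), although the cytoskeleton and matrix list passed without the 680 s, 2.6 mW, 4.2x library (adjusted p = 0.0319 with the preset correlation). The proteasome list had a median of 1.00, above the 0.88 of the other genes, while its camera direction was down. Fry on scaled libraries gave p-values from 0.0136 for the stress genes to 0.76 for the proteasome genes.

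After scaling, which moved the median change from 0.88 to -0.06, limma found 0 of 3203 genes that departed from the median, with 578 at an unadjusted p under 0.05, so smaller departures are not excluded. In the self-test, 86% of 2-fold changes were recovered, but its genes all had the same spread, so 2-fold departures are not excluded by it. Library totals rose 2.44-fold on average, a log2 ratio of 1.28 ± 0.77 (SD, n = 6 pairs, exact sign-flip p = 0.0312, the smallest possible). The number of listed intervals and the mean value per covered position both moved, with log2 ratios of 0.88 and 0.31. Without the 30 s libraries 1177 genes were higher and without the 180 s libraries 1509. Without the 680 s libraries 78 genes departed from the median, and 50 did without the 680 s, 2.6 mW, 1x library alone and 10 without the 680 s, 1 mW, 4.2x library.

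**Figure D2:**
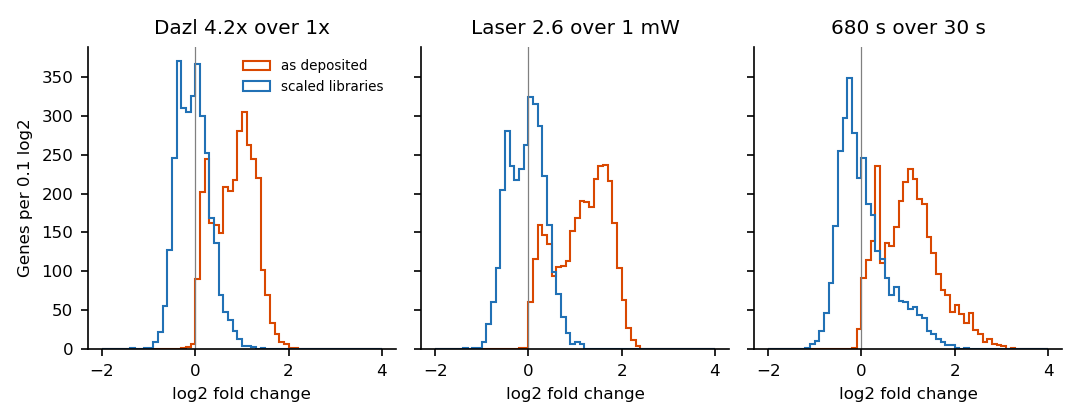
Histograms of the log2 fold change of 3203 genes with Dazl level, laser power and time, in bins of 0.1, from values as deposited and from scaled libraries; values beyond -2 or 4 are drawn at the edge. As deposited, the medians lie at 0.88, 1.22 and 1.03, and after scaling at -0.06, -0.01 and -0.05.

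Comparing 2.6 with 1 mW asks how coverage responds to light. Coverage rose with laser power on more genes than with Dazl level. Of 3203 genes, 2993 (93.4%) were higher at 2.6 mW and 0 lower, with a median change of 1.22 (2.33-fold). Malat1 rose by 2.11 ± 0.43 (adjusted p = 1.1e-05), Sdc4 by 2.01 ± 0.42, Canx by 1.95 ± 0.42, Timp2 by 1.94 ± 0.43 and Neat1 by 1.73 ± 0.44, each in 6 of 6 pairs. At 180 s and 1x Dazl, Canx went from 46 to 475 and Timp2 from 44 to 532. All 33 cytoskeleton and matrix genes, all 20 ribosomal protein genes, all 16 translation factors, all 12 cell cycle genes, all 9 decay factors and all 8 nuclear and small noncoding RNAs rose, and so did 28 of 29 RNA-binding protein genes, 9 of 10 stress genes and 5 of 6 proteasome genes, with the same counts adjusted over the list alone.

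Cytoskeleton and matrix genes and ribosomal protein genes had larger log2 changes than other genes, in a comparison not matched on coverage. Fold changes understate the change of low genes, so a difference in coverage was not separated from list membership. The matrix list had a median change of 1.71 against 1.22 in the other genes, and the ribosomal list 1.58, each with a camera adjusted p of 0.0387. With an estimated correlation the adjusted p was 0.821 for both. Among ribosomal protein genes Rps3 rose by 2.05 ± 0.38, with 2 of its 11 regions also in another gene, Rplp0 by 2.03 ± 0.38 and Rpl22 by 1.65 ± 0.35. On scaled libraries the same lists stood at 0.14 and 0.22, with adjusted p of 0.0353 and 0.0469 (both 0.290 with an estimated correlation). Their fry p-values there were 0.0392 and 0.0233, and the lowest of any list was 0.000383, for the cell cycle genes. Jund, a subunit of the AP-1 transcription factor, rose by 2.01 ± 0.40, Hsp90ab1, a cytosolic chaperone, by 1.71 ± 0.36, and Psmb7, a proteasome subunit, by 0.63 ± 0.30 in 4 of 6 pairs. The histone genes H4c11 (2.02 ± 0.30) and H2ac8 (1.85 ± 0.32) belong to families of near-identical copies, and their reads may be shared. The germ cell genes Mov10l1, Rhox13 and Sall4 rose by 0.40 ± 0.10, 0.35 ± 0.08 and 0.31 ± 0.08 with coverages of 1 to 4 over all libraries, and Rhox13 and Sall4 are among the 412 genes at the lowest value. The marker genes Wt1 (1.35 ± 0.27) and Dhh (1.08 ± 0.27) rose and Kdr (0.23 ± 0.15, adjusted p = 0.121) did not pass.

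Library totals rose 3.48-fold with laser power, a log2 ratio of 1.80 ± 0.86 (SD, n = 6 pairs, exact sign-flip p = 0.0312). After scaling, limma found 0 genes that departed from the median, with 934 at an unadjusted p under 0.05. That count rested on libraries of 680 s: it was 455 without the 680 s, 2.6 mW, 4.2x library, 55 without the 680 s, 1 mW, 4.2x library and 126 without all libraries of 680 s. The list calls were lost on leaving out single libraries, with 0 lists past the threshold without the 30 s library of 1 mW and 1x Dazl, or without any one of the 30 s and 180 s libraries of 2.6 mW, and 1 list without the 180 s library of 1 mW and 1x Dazl.

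The comparison of 680 with 30 s asks how coverage accumulates during crosslinking. Coverage rose on 2339 of 3203 genes (73.0%) and fell on 0, with a median change of 1.03 (2.04-fold). A slope on log2 time gave 1224 genes, and 5 of 100 permutations of the times gave as many as the real order, so chance was not excluded for this count. Genes differed in how much of their listed coverage was already present at 30 s. Those named next have between 1 and 3 regions each. Regions of 1 gene were only weakly alike in this share (intraclass correlation 0.035). The RNAs that rose most relative to the median were Tnpo3, the nuclear import receptor of splicing factors, Cflar, an inhibitor of caspase 8 at death receptors, Ints1, a subunit of the Integrator complex, Ndfip1, an adaptor of Nedd4-type ubiquitin ligases, Tgfbr2, a receptor of transforming growth factor beta, Ppie, a cyclophilin of the spliceosome, and the histone genes H4c2 and H4c8. Those that fell relative to the median were Mpdz, a scaffold protein with many PDZ domains, Blcap, Sympk, a scaffold of the polyadenylation machinery, Zfp609, Klhl42, Sh3glb1, a membrane-bending protein of the endophilin family, Atrn and Akap13, an anchoring protein of protein kinase A. In all, 357 genes departed from the median change, 305 upward and 52 downward. The downward count was 12 without the 680 s, 1 mW, 1x library and 21 without the 680 s, 1 mW, 4.2x library. It was 13 and 40 without the 680 s libraries of 2.6 mW at 1x and 4.2x. The highest, 75, came without the 180 s, 2.6 mW, 1x library.

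Tnpo3 had a coverage of 15 at 30 s, 51 at 180 s and 130 at 680 s with 2.6 mW and 4.2x Dazl, and 3, 3 and 75 with 1 mW and 4.2x Dazl. Its departure was 1.96 ± 0.27 (SE, log2, adjusted p = 0.000489). Cflar had 6, 13 and 92 at 2.6 mW and 4.2x, and departed by 1.85 ± 0.33 (adjusted p = 0.00275). Ints1 had 11, 26 and 55, in 1 region at 139759273 to 139759289 of chromosome 5, and departed by 1.72 ± 0.34. Tgfbr2 had 7, 28 and 87 and Ppie had 12, 38 and 91, with departures of 1.67 ± 0.30 and 1.66 ± 0.32. Ndfip1 departed by 1.68 ± 0.35, with 10, 18 and 63. H4c2 and H4c8 departed by 1.71 ± 0.28 and 1.69 ± 0.41, and as members of a family of near-identical histone H4 genes they are uncertain. Each was higher in 4 of 4 blocks, which the rule for naming genes required. Every region of these 8 genes was at 1 at 30 s and 180 s with 1 mW and 1x Dazl, and at 1 or 2 with 1 mW and 4.2x Dazl, so the size of their departures depends on the lowest value and the pseudocount.

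The genes that fell relative to the median had most of their coverage at 30 s. With 2.6 mW and 4.2x Dazl, Mpdz had 36, 35 and 36 at the 3 times, Sh3glb1 had 30, 30 and 30, Blcap 81, 76 and 81, Sympk 42, 35 and 43, and Zfp609 47, 43 and 47. The single Mpdz region lies at 81361397 to 81361413 of chromosome 4, 81484 nt from the nearer end of the gene, and that of Sh3glb1 at 144687871 to 144687887 of chromosome 3. At 1 mW and 4.2x Dazl, Mpdz had 20, 11 and 16 and Klhl42 had 30, 12 and 27. The departures were -1.10 ± 0.29 for Mpdz (adjusted p = 0.0196), -1.08 ± 0.20 for Blcap (adjusted p = 0.00318), -1.05 ± 0.24 for Sympk, -1.05 ± 0.25 for Zfp609, -1.03 ± 0.23 for Klhl42, -0.99 ± 0.27 for Sh3glb1, -0.93 ± 0.24 for Atrn and -0.91 ± 0.21 for Akap13. In the 2.6 mW, 4.2x series, 45.4% of regions with at least 10 at 680 s had exactly the same value at 30 s and 0 regions had a lower value at 680 s, so the deposited values are tied between these libraries and a flat course there is not shown to be an independent measurement. Without the 30 s library of that series, 294 genes departed from the median. On values as deposited, none of these 8 passed the test between 30 and 680 s (Mpdz 0.00 ± 0.34, Blcap 0.16 ± 0.39, Akap13 0.33 ± 0.39).

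**Figure D3:**
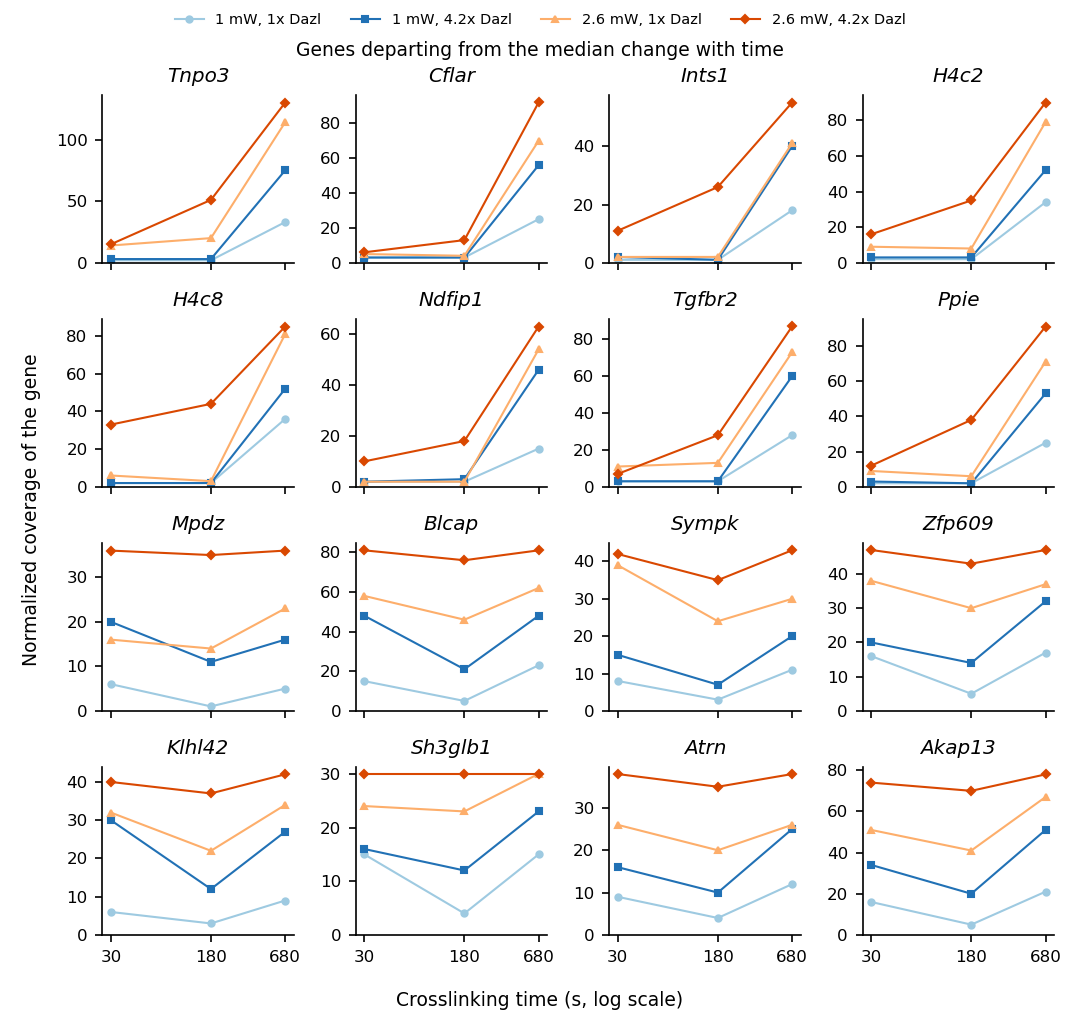
Normalized coverage of the 16 named genes against crosslinking time (log scale), with 1 library per point and lines joining libraries of equal laser power and Dazl level. The upper 8 genes make most of their rise after 180 s, as Tnpo3 does from 51 to 130 at 2.6 mW and 4.2x Dazl, and the lower 8 are near their 680 s coverage at 30 s in that series.

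**Figure D4:**
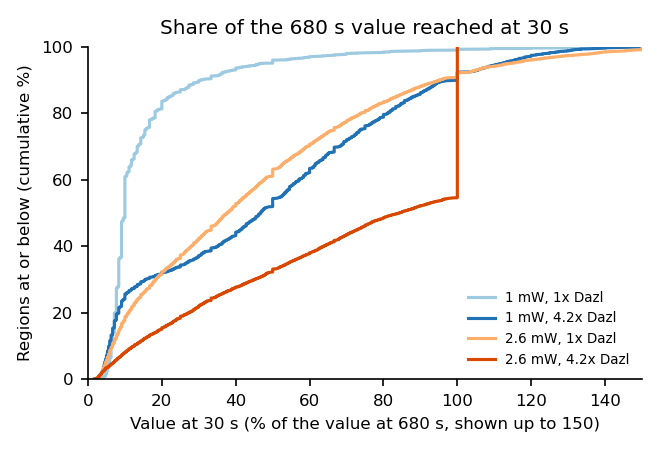
Cumulative percent of regions (vertical) by their value at 30 s as a percent of the value at 680 s (horizontal, shown up to 150), for regions with at least 10 at 680 s in each series of laser power and Dazl level. The step at 100 in the 2.6 mW, 4.2x series is the 3318 regions with exactly equal values at both times.

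No gene list departed from the other genes with time (lowest camera adjusted p = 0.71 as deposited and 0.725 on scaled libraries; 0.946 and 0.727 with an estimated correlation). As deposited, 29 of 33 cytoskeleton and matrix genes, 24 of 29 RNA-binding protein genes, 17 of 20 ribosomal protein genes, 12 of 16 translation factors, 10 of 12 cell cycle genes, 9 of 10 stress genes, 7 of 8 noncoding RNAs, 6 of 9 decay factors and 3 of 6 proteasome genes rose. Adjusted over the list alone these were 30, 24, 18, 12, 10, 9, 7, 6 and 3. Examples were Eif1a (1.66 ± 0.43), Hsp90ab1 (1.66 ± 0.44), Malat1 (1.81 ± 0.53) and Neat1 (1.36 ± 0.53). The markers Wt1 (1.53 ± 0.33), Dhh (1.72 ± 0.33) and Kdr (0.87 ± 0.18) rose. The germ cell genes Mov10l1 (0.21 ± 0.12), Rhox13 (0.16 ± 0.10) and Sall4 (0.15 ± 0.09) did not pass.

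Library totals at 680 s were 2.44-fold those at 30 s, a log2 ratio of 1.29 ± 0.80 (SD, n = 4 blocks, exact permutation p = 0.0417), while the slope of log2 total on log2 time had an exact permutation p of 0.0725. The 180 s total was below the 30 s total in 3 of the 4 series, with ratios of 0.76, 0.65 and 0.93, and above it only at 2.6 mW and 4.2x Dazl (1.07). The count of departing genes was 940 (603 upward, 337 downward) without the 1 mW, 1x libraries of 30 s and 180 s, an alternative chosen after seeing the data. It fell to 172 without the 30 s, 1 mW, 4.2x library, 189 without the 30 s, 2.6 mW, 1x library, 208 without the 680 s, 2.6 mW, 1x library and 224 without the 680 s, 1 mW, 4.2x library, and quantile normalization gave 737 (385 upward, 352 downward).

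Whether the Dazl effect differed between laser powers or times was tested with interaction terms. Lrrc28, a leucine-rich repeat protein gene, was the only gene whose Dazl effect differed between laser powers on values as deposited, and it was named after its values were seen. Its single region had 1, 1 and 11 at the 3 times with 1 mW and 1x Dazl and 41, 33 and 53 with 1 mW and 4.2x Dazl. At 2.6 mW it had 51, 69 and 80 with 1x and 83, 83 and 83 with 4.2x (interaction -2.55, limma adjusted p = 0.0438). Lrrc28 lost its call with a pseudocount of 30 (-0.84, adjusted p = 0.413), where 0 genes passed. It also lost it without the 1 mW, 1x libraries of 30 s and 180 s (-1.55, adjusted p = 0.459), an alternative chosen after seeing the data, where 14 other genes passed. At an unadjusted p under 0.05 there were 486 genes, and 63.4% of all interaction terms were negative, with a median of -0.26. On scaled libraries 73 genes passed (21 with a larger and 52 with a smaller Dazl effect at 2.6 mW) and 855 had an unadjusted p under 0.05, but 44.9% of the terms were negative and their median was 0.11, so the sign of the typical term depends on the scaling. No gene had a Dazl effect that differed with log2 time, with 224 at an unadjusted p under 0.05. For library totals the Dazl ratio averaged 3.46-fold at 1 mW and 1.71-fold at 2.6 mW, and was higher at 1 mW at each of the 3 times. The exact permutation test of this difference (p = 0.2, n = 3 pairs each) cannot go below 0.1 and ignores the matching by time, so it decides nothing. By pair, the ratio was 5.00, 4.29 and 1.93 at 30, 180 and 680 s with 1 mW, and 1.89, 2.16 and 1.24 with 2.6 mW.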

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

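The tests of the laser effect against time, those of the 180 s totals at 1x Dazl, and those of the floor at 30 s and 180 s, were chosen only after results were seen, and the others were set beforehand. The Dazl effect differed between laser powers in 1 gene on values as deposited, Lrrc28, and in 73 genes on scaled libraries (21 larger and 52 smaller at 2.6 mW), by an interaction term. Examples on scaled libraries, named after their values were seen, were Lrrc28 (-2.64), Ankrd12 (-2.22), Dynll2 (-1.48) and Ube2z (-1.48). For the single gene, the 10 splits of the matched pairs are too few for a share under 0.05; the real split gave 1 gene and the highest other gave 0. The laser effect differed between times in 3 genes on values as deposited, Rbm38 (0.27, adjusted p = 0.00225), Fam13a (0.30, adjusted p = 0.0481) and Xrn2 (0.32, adjusted p = 0.0481), named after their values were seen. On scaled libraries limma found 0 such genes, with 154 at an unadjusted p under 0.05, and these terms rest on the lowest values, since coverage of Fam13a ran only from 1 to 8 and Rbm38 and Xrn2 were at 1 in all 8 libraries of 30 s and 180 s. Of the regions, 186 lie in no gene of the table and entered no gene test.

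Other splits of the libraries were fitted for each count. The real labels gave the most genes changed with Dazl level (1 of 32 splits, 2640 genes, highest other 1804). They did so too with laser power (1 of 32 splits, 2993 genes, highest other 2080). The same held for the genes departing from the median with time (1 of 100 permutations, 357 genes, highest other 170). The real labels are 1 of the splits counted, so each of these shares is the smallest possible. Other splits of the same libraries also called many genes, so chance is made less likely but is not excluded. For the genes changed with time on values as deposited, 5 of 100 permutations gave as many (2339 genes, highest other 2678), so chance stays open there. For the counts of 0 the splits decide nothing, since every split gives at least 0: 32 of 32 for genes departing with Dazl level and 32 of 32 with laser power (highest other 0 in each), and 90 of 90 assignments for the interaction of Dazl level and time (highest other 70). These splits take the libraries as exchangeable, which the order and ties of their values leave in doubt.

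Library totals were lower at 180 s than at 30 s in 3 series and higher in the other, with log2 ratios of -0.404 at 1 mW and 1x, -0.625 at 1 mW and 4.2x, -0.1 at 2.6 mW and 1x, and 0.094 at 2.6 mW and 4.2x, a difference between series that was not tested. At 1 mW and 4.2x, regions at the lowest value do not account for the drop, since the median ratio was -0.637 over 3356 regions above 5 at both times, and nor do a few genes, since the log2 ratio of totals was -0.627 without the 10 highest genes. At 1x Dazl a few genes do not account for it. Without the 10 highest genes the log2 ratio was -0.394 at 1 mW and -0.102 at 2.6 mW. With regions at the lowest value set to 0 it was -0.937 and -0.111, which decides nothing. At the lowest value were 6709 regions at 180 s and 6174 at 30 s with 1 mW, and 1948 and 1372 with 2.6 mW. Setting them to 0 could therefore only deepen the drop. At 1 mW and 4.2x a scale factor set per library by the normalization stays open. Regions were grouped by the share of their 680 s value reached at 30 s with 2.6 mW and 4.2x. The groups of equal size set beforehand could not be formed, because the upper cutoff fell on the tied value of 100%. The upper group held 2142 regions, and the lower group, cut at 76.6%, held 840. Their median log2 ratios, 180 s over 30 s, were -0.585 and -0.737, a difference of 0.152 (0.115 to 0.190, 95% bootstrap interval). The interval leaves out 0 and lies within the bound of 0.2 set beforehand. That bound was set for other groups, so it decides nothing here. A change common to all RNAs in the cells would give the same values, and no biological explanation was tested.

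The Dazl ratio of totals was 3.46-fold at 1 mW and 1.71-fold at 2.6 mW, with the higher ratio at 1 mW at each of the 3 times, and an exact test that cannot go below 0.1. At 680 s the log2 Dazl ratio of totals was 0.952 at 1 mW and 0.307 at 2.6 mW. Values at the floor of the 1 mW, 1x library are argued against as the only source of this difference. Over 5681 regions above 5 in all 4 libraries the median difference in log2 ratio was 0.489 (0.475 to 0.508, bootstrap over regions). That interval measures spread between regions of these 4 single libraries, not between repeats of the conditions. With regions at the lowest value set to 0, the difference was 2.116 at 30 s and 2.188 at 180 s. As deposited it was 1.407 and 0.991. This cannot test the floor. The 1 mW, 1x libraries hold the most such regions (74.0% and 80.5%), so the outcome followed from those counts. It shows only that counting such regions as 1 did not enlarge the difference. Regions already near their highest value at 2.6 mW and 4.2x stay open: the rho of 0.008 with the share at 1 mW does not exclude them as set beforehand, because a ceiling common to all regions also gives a rho near 0, and 45.4% of regions with at least 10 at 680 s were equal at 30 and 680 s there. A scale factor per library stays open too and was not tested.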

How the results depend on the processing

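The alternatives without the 1 mW, 1x libraries of 30 s and 180 s and without the genes at the lowest value, and leaving out libraries for the gene lists, were chosen only after seeing the data. Of 203 alternatives for counts, lists and totals, 156 were labelled the same, 30 weaker, 17 stronger and 0 reversed. Totals were judged by direction and side of the threshold. Counts of genes and lists were judged only by a set fold range around the main count, so they could not be reversed. For 140 results of named genes, 3004 alternatives were the same, 289 weaker, 13 stronger and 29 reversed, by side of the threshold and direction. Direction was judged only for results past the threshold. The cause was not tested except where said. Filters on listed libraries removed no gene. Comparisons of 3 prime untranslated regions, GTT content and read-count tools were not run. Depth in reads is unknown, so no counting interval is given. No alternative run here removes the order and ties of the values.

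Without the 30 s, 180 s and 680 s libraries and without the 1 mW, 1x libraries of 30 s and 180 s, the Dazl log2 ratio of totals was 1.117, 1.124, 1.612 and 0.821 and the laser ratio 1.738, 1.483, 2.181 and 1.311, all with an exact p of 0.125, the smallest that 4 pairs allow. The time ratio was 0.255 for the mean value per covered position (exact permutation p = 0.0586) and 0.911 without the 1 mW, 1x libraries of 30 s and 180 s (exact permutation p = 0.0926).

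With regions as the unit, more items were tested: 6224 changed with Dazl level, 7628 with laser power and 5125 with time, and 29, 30 (24 higher, 6 lower) and 1280 (1118 higher, 162 lower) departed from the median. With each library scaled to the same total, which removes a common change, 0 genes changed with Dazl level, 0 with laser power and 362 with time (312 higher, 50 lower). Genes changed with Dazl level were 1177 without the 30 s libraries and 1509 without the 180 s libraries. Without the 680 s libraries 78 (67 higher, 11 lower) departed with Dazl level and 126 (71 higher, 55 lower) with laser power. Quantile normalization gave 2 departing with Dazl level and 737 with time (385 higher, 352 lower). A slope on log2 time gave 1224 changed and 236 departing (195 higher, 41 lower). Without the 1 mW, 1x libraries of 30 s and 180 s, 940 departed with time, 14 genes had an interaction of Dazl level and laser power, 4 of Dazl level and time, and 1 gene list passed. Without the 412 genes at the lowest value, 2333 changed with Dazl level, 2651 with laser power and 2158 with time, and 359 (256 higher, 103 lower) departed with time. The first interaction had 0 genes with a pseudocount of 30, and 0 gene lists passed with an estimated correlation.

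Leaving out 1 library at a time, gene lists past the threshold ranged from 0 to 3 (3 without the 680 s, 2.6 mW, 4.2x library, one of them for Dazl level), departing genes from 0 to 50 with Dazl level, 0 to 455 with laser power and 172 to 481 with time, and changed genes from 2225 to 2625, 2794 to 3011 and 1678 to 2627. The libraries behind these ranges were: for Dazl level, 680 s, 2.6 mW, 1x (50) and 680 s, 1 mW, 4.2x (10); for laser power, 680 s, 2.6 mW, 4.2x (455) and 680 s, 1 mW, 4.2x (55); for time, 30 s, 1 mW, 4.2x (172), 30 s, 2.6 mW, 1x (189), 680 s, 2.6 mW, 1x (208) and 680 s, 1 mW, 4.2x (224). Calls among the time genes were lost in 4 of 24 alternatives for Mpdz, 3 for Atrn, 3 for Sh3glb1 and 2 for H4c8.

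All 29 reversals came with each library scaled to the same total, which turns genes below the common change negative by construction, and none passed the threshold there (lowest adjusted p = 0.152). With Dazl level they were Thbs1 -0.002, Scd2 -0.051, Pdia3 -0.027, Cdkn1b -0.115, Mov10l1 -0.326, Tob1 -0.065, H4c8 -0.065, Rpl22 -0.059 and Hsp90aa1 -0.11. With laser power they were Neat1 -0.054, Thbs1 -0.052, Ccnd1 -0.02, Mov10l1 -0.389, Rhox13 -0.393, Sall4 -0.391, Snhg1 -0.073, Psmb7 -0.887, Dhh -0.036 and Hsp90aa1 -0.04. With time they were Thbs1 -0.149, Pdia3 -0.105, Cnot6 -0.057, Pan3 -0.026, H2ac8 -0.099, Rpl22 -0.187, Hnrnpk -0.204, Srsf6 -0.086, Jund -0.122 and Hsp90aa1 -0.111.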

Other observations

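The tests here were set before their results were seen, except that of the level at 2.6 mW and 1x, and the counts of ties were made afterwards. Regions differed in the share of their 680 s value reached at 30 s. At 2.6 mW and 4.2x Dazl the median share was 84.1%, with 47.9% of regions at 90% or more and 15.0% under 20%. In the other series the medians were 10.0% at 1 mW and 1x, 46.7% at 1 mW and 4.2x and 37.5% at 2.6 mW and 1x. Shares also spread within 1 RNA: the 61 regions of Neat1 with at least 10 at 680 s ran from 3.4% to 100% with a median of 71.0%, and the 38 of Malat1 from 2.0% to 100% with a median of 52.0%. Col1a1, Timp2 and Sdc4 had medians of 100%, Canx 91.0%, Pdia3 87.5%, Thbs1 85.3%, Scd2 73.3% and Tm9sf3 66.0%.

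A property of the region that repeats between laser powers may underlie these shares, as a hypothesis. The share at 4.2x and 2.6 mW had a Spearman rho of 0.596 with the share at 4.2x and 1 mW across 6773 regions, which are not independent replicates. Regions of 1 gene were more alike than shuffled ones (permutation p = 0.0001, the smallest that 10000 shuffles can give), but with an intraclass correlation of only 0.035. The level of the region stays open: its rho with the share was -0.087 for the 680 s value at 2.6 mW and 4.2x, which is the denominator of the share, and -0.075 for the 680 s value at 2.6 mW and 1x, which follows that denominator (rho 0.93). The correlated shares use different libraries, but values are ordered within each series, and between series, as described next. A processing step that links libraries could therefore give the same repeat and stays open.

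At 2.6 mW and 4.2x Dazl, 3318 regions (45.4%) had exactly equal whole values at 30 and 680 s, and 778 (10.7%) at 180 and 680 s, against 5.2% and 5.3% in independent Poisson draws. None of the 8338 regions was lower at 680 s than at 30 s or 180 s in that series, where draws gave 1989 and 1831. In the 2.6 mW, 1x series 666 and 49 were lower (draws 1027 and 706), and in the 1 mW, 4.2x series 607 and 0 (draws 1177 and 374). In the 1 mW, 1x series 73 and 0 were lower (draws 522 and 432). In these 3 series equal values made up 0.0% to 2.5% of regions, fewer than the 5.7% to 7.6% of draws around 1 mean, which leave out the change with time. Across all 12 libraries, 96.8% of regions were at their highest value in the 680 s, 2.6 mW, 4.2x library, ties counted. Values were ordered between series too. At 30, 180 and 680 s, 2.2%, 0.6% and 0.0% of regions were lower at 2.6 than at 1 mW with 1x Dazl. With 4.2x Dazl these were 5.7%, 0.0% and 0.0%. Lower at 4.2x than at 1x Dazl were 2.7%, 0.6% and 1.4% at 1 mW, and 10.7%, 0.3% and 0.0% at 2.6 mW. No draws were made for these shares, so the part that follows from the rise itself is not known.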
